A study of Homo sapiens with 2 samples.

How the data were processed

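ATAC-seq libraries of H1299 cells were compared, 1 from an untreated culture and 1 from a culture given 5 mM metformin, grouped by the treatment stated in the labels. The assay was carried out by a commercial service, per the labels' protocols. The submitters' processing notes name BWA, MACS2 and DESeq2 with no version, role or order, and the build hg38. The peak caller's threshold, the removal of duplicates, the shift of reads for the transposase and any scaling between libraries are not given in the sources used here. Each of these could move the values: without the removal of duplicates, for example, amplified fragments raise the signal of single regions.

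The deposited table lists the peaks of each library separately, with no pooling, so that a region can have a peak in 1 library and no value in the other. Its main measurement is a signal: the authors gave, for each peak, the signal of the highest bin of about 32 bases and the mean signal over the bins of the peak. In the deposited table the highest-bin signal is a whole number of at least 16, and the mean signal times the number of bins is within 0.02 of a whole number in 99.9% of peaks of both libraries. Whole values can also come from rounding after scaling, so this does not show whether a factor per library was applied. Whether the libraries were brought to the same depth is not stated, and the total number of fragments is unknown. For this reason a signal was not treated as a count, no count model was used, and no interval for counting error is given. Comparing signals between libraries rests on the shared bin width and unit alone, and a factor common to all regions would shift all log2 ratios by the same amount. The table also holds the authors' peak lengths, bin numbers, CpG island numbers and gene annotation, with the distance to a gene's start and whether the peak is inside, upstream or downstream of it.

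The 108183 peaks of both libraries were merged into 60335 regions wherever they overlapped by at least 1 base, and 828 regions (1.37%) joined several peaks of the same library. A region's value in a library was the highest highest-bin signal among its peaks. The log2 ratio was log2 of the metformin signal plus 1 minus log2 of the control signal plus 1, which was computed for the 46984 regions with peaks in both libraries. A region was called higher or lower at a ratio of at least 2-fold if the mean of its 2 signals was at or above the median of 97.5. Promoter regions lay within 1000 bases of an annotated start and distal regions over 10000 bases from any, by the authors' annotation. Coordinates are 1-based on hg38. Gene symbols are those of the authors' annotation, brought to current symbols for matching lists with a table of gene names made for GRCh38.p14, which was used for names only: 23332 of 27471 symbols matched.

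With 1 library per treatment no test, leave-one-out or paired comparison could be made, and differences between regions or lists are descriptions of these libraries. For gene lists, each gene took the region nearest to its start within 1000 bases if it passed the filter. The median of a list's log2 ratios was placed among 10000 random lists of the same size, drawn from all 13034 such genes and matched on signal deciles. A list stood apart when it had at least 8 measured members and its median lay under the 2.5 or over the 97.5 percentile, which chance gives for 5% of lists. Genes of a list can share regulation or a region, so a percentile is not a p-value. The 24 lists, the thresholds, the rule for named genes and most alternatives were set before the data were examined. The rule named the 10 regions with the highest and the 10 with the lowest log2 ratio that lay within 10000 bases of a named gene's start or inside it, the 4 leading members of each list that stood apart, the 2 members with the largest ratios of each other list, and 6 chosen genes each of the AMPK and DNA methylation lists. Some genes that the rule names are not reported here. Genes named outside it are marked as such, apart from members of the fixed lists called in 1 library only, all 8 of which are given. Shares have exact Clopper-Pearson 95% intervals, and differences of medians have bootstrap intervals over 1000 draws of regions. Random sets of regions were drawn from the 23557 regions, each from the same 1 of 20 bins of mean signal as the region it replaced.

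The plan had assumed 1 merged table of normalized values. The highest-bin signal was chosen as the main value after the columns were seen, with the mean over bins as the alternative, and regions with a value in 1 library only were given no ratio. The filter on signal was applied to the counts of higher and lower regions and to lists, while promoter, distal and chromosome medians used all regions, with the filter as an alternative. Alternatives tried were scaling to a median ratio of 0, lowess centring on signal (span 0.3), other signal filters, a pseudocount of 5, fold thresholds of 1.5 and 3, autosomes only, a promoter definition of 2500 bases, all regions of a gene, and random lists matched also on length. A planned comparison of 22 sequence motifs needs the genome sequence and was not run.

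The steps were tested on simulated data. In 46984 simulated regions drawn by Poisson sampling from the mean signals, which takes 1 unit of signal as 1 fragment although no source states this, 0% of regions changed 1.5-fold, 98.5% of those changed 2.5-fold and 100% of those changed 4-fold were called, and 0% of unchanged regions. The changed regions were all at or above the median signal, while the unchanged ones included weaker regions that the filter never calls. Poisson draws also spread less than the data (SD of the log2 ratio 0.145 against 0.253). The 0% of unchanged regions therefore does not carry over to the data. Of 200 random lists of 25 of the 13034 genes, 6.5% stood apart with no shift and 96.5% with a shift of −0.15. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.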

Results

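Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in H1299 cells, a human non-small cell lung cancer line that lacks functional p53. One culture was untreated and the other received 5 mM metformin, a biguanide used against type 2 diabetes that inhibits respiratory complex I. The length of the treatment is not given in the sources used here. Each treatment had 1 library, so no spread between replicates exists, no test between treatments was possible, and every value below describes these 2 libraries. The control library had 54754 peaks covering 25.3 Mb of hg38 and the metformin library 53429 peaks covering 24.2 Mb. The median signal in the highest bin of a peak was 84 in the control library and 82 in the metformin library. How many fragments 1 unit of signal stands for is not stated, so no counting interval could be attached to a signal. The authors' scaling between the libraries is not stated either, and over the 46984 regions with a value in both libraries the median log2 ratio of metformin to control was −0.10. Ratios are therefore read against the other regions of the same pair of libraries.

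The first question was which regions were open in each culture. Most accessible regions were shared: of 60335 merged regions, 46984 (77.9%) were called in both libraries, 7473 (12.4%) in the control library only and 5878 (9.74%) in the metformin library only. Regions called in 1 library were mostly weak and lay away from genes' starts. Their median signal was 33 for control only and 31 for metformin only, while shared regions had an interquartile range of 52.5 to 209, and promoters made up 13.4% and 7.55% of them, against 29.4% of shared regions. Among the genes of the lists fixed in advance, a weak promoter region was called in the control library only at NUPR1, a stress-induced transcriptional regulator (signal 26), at SLC47A2, a transporter that exports metformin (46), at PRKAG3, a regulatory subunit of AMPK (33), at ALDH1A3, a retinaldehyde dehydrogenase (38), and at SFTPD, a lung surfactant protein (37). In the metformin library only, such regions were called at the glycolytic genes PFKFB4 (43) and ALDOC (36) and at TET3, an enzyme that oxidises 5-methylcytosine (48). At or above the median signal of shared regions, 284 control-only and 194 metformin-only regions remained, and 141 and 67 of these lay within 500 bases of a peak of the other library.

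The second question was which regions differed most between the cultures. Among the strongly lower regions in the metformin library were the promoter of TRIB3, a pseudokinase induced by the transcription factor ATF4, and the promoter of SMAD1, a transducer of bone morphogenetic protein signals. Regions inside LINC01512, a long non-coding RNA gene, and inside PHACTR4, a phosphatase and actin regulator, had the lowest ratios among regions at or above the median signal. Strongly higher regions lay inside PUS7L, a relative of pseudouridine synthases, and SASH1, a scaffold protein, and beside TM4SF1, a cell surface protein of the tetraspanin-like family. Of 23557 regions at or above the median signal, 60 were at least 2-fold lower and 26 at least 2-fold higher in the metformin library. That split depended on scaling: the lower regions made up 69.8% of the 86 as deposited, but after the median ratio was set to 0 there were 30 lower and 47 higher regions and the lower share was 39.0%.

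The lowest ratio belonged to a region of chromosome 6, 43910666 to 43911064, annotated by the authors as inside LINC01512, 19820 bases from its start, where the signal was 183 in the control library and 43 in the metformin library (log2 ratio −2.06). In PHACTR4, a region 47922 bases from the start (chromosome 1, 28417336 to 28417734) had signals of 205 and 55 (−1.88). The promoter region of TMEM63C, a multi-pass membrane protein, at chromosome 14, 77181418 to 77181988, had 266 and 82 (−1.69). A region 1115 bases inside SARS, the cytosolic seryl-tRNA synthetase gene, at chromosome 1, 109214826 to 109215170, had 184 and 59 (−1.62). At TRIB3 the region lay 171 bases inside the gene (chromosome 20, 380616 to 381184) in a CpG island, with signals of 217 and 71 (−1.60). The promoter region of SMAD1 at chromosome 4, 145481562 to 145482009, had 161 and 58 (−1.46). The other 4 named lower regions lay inside PGPEP1, a pyroglutamyl peptidase (−1.55), SPTBN4, a beta spectrin (−1.50), and ARHGEF2, a microtubule-associated signalling protein (−1.50), and upstream of NSA2, a ribosome biogenesis factor (−1.46).

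On the higher side, a region of PUS7L at chromosome 12, 43742101 to 43742488, 16545 bases inside the gene, had signals of 62 in the control library and 195 in the metformin library (1.64). A region of TMEM117 further along the same chromosome, 43816177 to 43816700, had 110 and 297 (1.42). The SASH1 region, 264320 bases inside the gene at chromosome 6, 148457448 to 148458056, had 93 and 286 (1.61). The region assigned to TM4SF1-AS1 and TM4SF1 at chromosome 3, 149368292 to 149368934, had 140 and 342 (1.28). The other named higher regions lay inside IQCJ (1.30), SCP2, a sterol carrier protein (1.26), MSN, the actin linker moesin (1.23), FGD6, an exchange factor for Cdc42 (1.20), BCAP29, a protein of the endoplasmic reticulum membrane (1.17), and C10orf55, a gene that shares its region with PLAU, the urokinase gene (1.12). With the mean signal over bins in place of the highest bin, the C10orf55 region was at 0.51 and the BCAP29 region at 0.81, below the 2-fold threshold. The authors' annotation gives positions as inside, upstream or downstream of a gene, and exons, introns and UTRs were not analysed here.

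**Figure D1:**
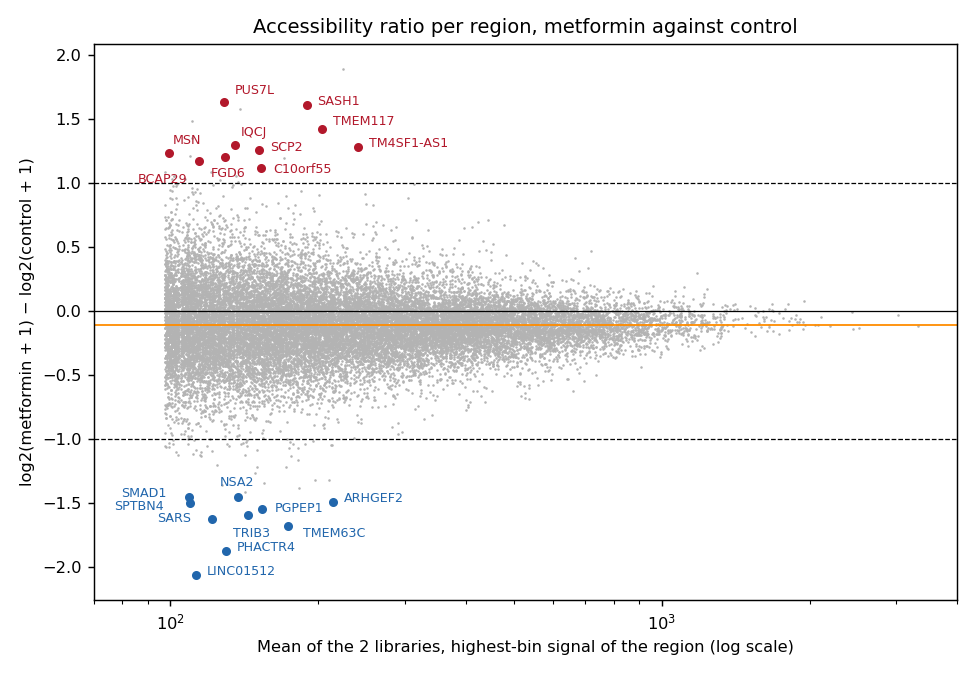
Log2 ratio of metformin to control (y axis) against the mean highest-bin signal of the 2 libraries (x axis, log scale) for the 23557 regions at or above the median signal, 1 grey point per region. Dashed lines mark the 2-fold thresholds and the orange line the median of −0.11; named higher regions are red and named lower regions blue, and the scatter of ratios is wider at low signal.

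The third question was whether promoters and distal regions differed in the same way. Higher regions were mostly distal: of the 26, 20 (76.9%, exact Clopper-Pearson 95% interval 56.4 to 91.0%) lay over 10000 bases from a start site, 6 lay between the 2 limits and 0 lay at a promoter (upper limit 13.2%). Lower regions included promoters such as TRIB3, SMAD1, TMEM63C and GDF15, a secreted stress cytokine, with 16 of 60 at promoters (26.7%, 16.1 to 39.7%) and 32 distal (53.3%, 40.0 to 66.3%). These intervals cover the sampling of regions only. Among all 23557 regions promoters made up 46.6% and distal regions 30.7%, but distal regions were weaker (median signal over all regions 66, against 228 at promoters), and ratios spread more at low signal. In 1000 random sets matched on signal to the higher regions, 43.2% of regions were distal (95% of sets between 23.1 and 61.5%) and 28.6% lay at promoters (11.5 to 46.2%), so the higher regions were outside both ranges. For the lower regions the sets had 42.0% distal (28.3 to 55%) and 30.4% at promoters (20 to 41.7%), and the observed shares were inside both. With the median ratio set to 0, 33 of 47 higher regions (70.2%) were distal and 1 lay at a promoter, and of 30 lower regions 18 (60.0%) were distal and 5 (16.7%) lay at promoters. No matched random sets were drawn for the regions called after scaling, so whether these shares are unusual for their signal was not checked. CpG islands overlapped 17 of the 60 lower regions as deposited (28.3%; matched sets 25 to 46.7%) and 0 of the 26 higher regions (15.4 to 50%). Over all regions, the median log2 ratio was −0.13 at 13803 promoter regions (interquartile range −0.26 to 0) and −0.07 at 22210 distal regions (−0.30 to 0.16). The difference of −0.05 (bootstrap 95% interval over regions −0.06 to −0.05) was small beside either interquartile range. CpG island regions had a median of −0.14 and regions without an island −0.07. Among island regions, promoters (11331) stood at −0.136 and distal regions (1694) at −0.153. Without an island, promoters (2472) stood at −0.080 and distal regions (20516) at −0.064. Promoters were thus not lower than distal regions among island regions, and only slightly lower among the others.

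The fourth question was whether promoters of genes of known pathways differed as groups. The ATF4 and integrated stress response list, genes switched on when cells lack amino acids or misfold proteins, lay lower than promoters of like signal. The lists of interferon response and antigen presentation and of cholesterol synthesis had medians above those of promoters of like signal. The respiratory complex I list did so less firmly, in 9 of 13 alternatives, some of which could not change its percentile. Over 13034 genes with a promoter region the median log2 ratio was −0.13, and each list's median was placed among 10000 random lists matched on signal. Of 19 lists with at least 8 measured members, 4 stood apart, where about 0.95 would by chance.

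In the stress response list, 18 of 25 measured members lay below the promoter median and 7 above. The list median was −0.25, against −0.12 for random lists (95% of them between −0.19 and −0.05), at percentile 0.02. TRIB3 and GDF15 were at least 2-fold lower as deposited. At GDF15 (chromosome 19, 18385986 to 18386379), in a region shared with MIR3189, the signal was 178 in the control library and 85 in the metformin library (−1.06), which became −0.96 with the median ratio set to 0. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (chromosome 14, 24093827 to 24094701), had 506 and 295 (−0.78). CEBPB, a transcription factor that partners ATF4 (chromosome 20, 50190360 to 50191423), had 240 and 150 (−0.67). The promoter of ATF4 itself, named here after its value was seen, stood at −0.13, close to the promoter median.

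**Figure D2:**
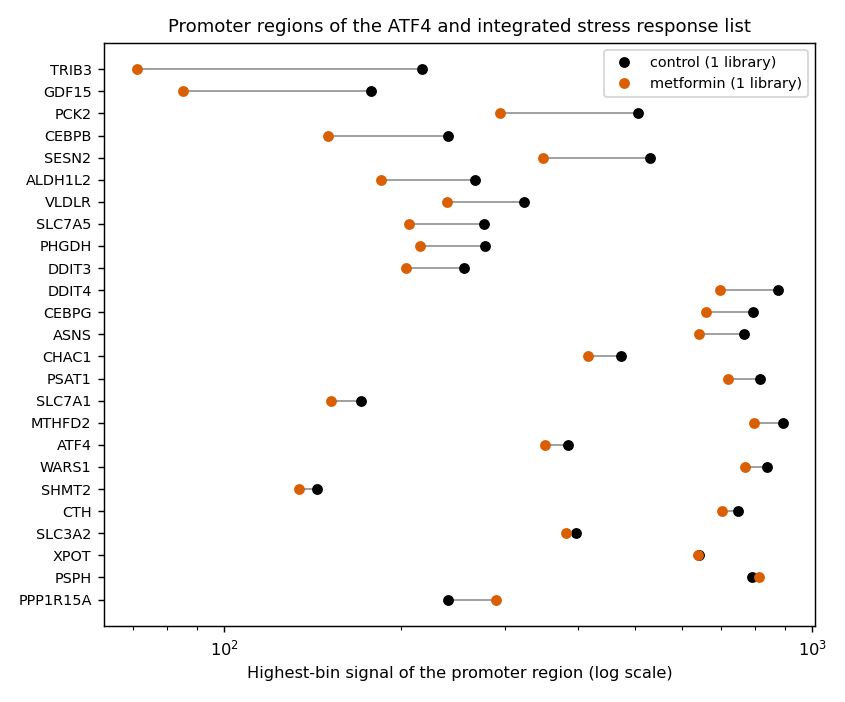
Highest-bin signal (x axis, log scale) of the promoter region of each of the 25 measured genes of the ATF4 and integrated stress response list, with black points for the control library and orange points for the metformin library. Genes run from the lowest log2 ratio at the top, TRIB3 at −1.60, to PPP1R15A at 0.27, and 18 of the 25 lay below the median of all promoters.

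In the interferon and antigen presentation list, 13 of 16 measured members lay above the promoter median (list median 0.02, random lists −0.13, percentile 99.96). PSMB8, a subunit of the immunoproteasome (chromosome 6, 32844265 to 32844964), had signals of 652 in the control library and 731 in the metformin library (0.16). In the same list HLA-E, a non-classical class I molecule, stood at 0.14 and IRF7, a regulator of type I interferon genes, at 0.13. The 3 members below the promoter median were TAP2, a peptide transporter (−0.33), HLA-B, a class I molecule (−0.28), and ISG15, a ubiquitin-like protein (−0.18). Of 5 members left out by the signal filter, the antiviral genes OASL (−0.68), MX1 (−0.48), IFIT2 (−0.41) and OAS3 (−0.32) were lower and IFIT3 (0.21) was higher in the metformin library. These 8 genes are named after their values were seen. In the cholesterol list, 15 of 22 lay above the promoter median (list median −0.03, random lists −0.12, percentile 99.6). DHCR7, the last enzyme of one branch of cholesterol synthesis (chromosome 11, 71448277 to 71448794), had 351 and 430 (0.29), STARD4, a sterol transfer protein, stood at 0.11, PMVK, phosphomevalonate kinase, at 0.10 and SC5D, a sterol desaturase, at 0.05. With the mean signal over bins the PMVK promoter stood at −0.20, and with all regions of each gene the cholesterol list was at percentile 96.9 and no longer stood apart.

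For complex I, a target of metformin, 19 of 34 measured subunit genes lay above the promoter median and 15 below (list median −0.06, random lists −0.13, percentile 98.0). NDUFAB1, an acyl carrier protein that is also a subunit, stood at 0.39, NDUFB1 at 0.35, NDUFS6 at 0.20 and NDUFA13 at 0.18. Among the 15 below the promoter median, NDUFB8 stood at −0.36 and NDUFB3, in a region shared with HYCC2, at −0.28, both named after their values were seen. The regions of NDUFB1, NDUFS6 and NDUFA13 are also assigned to the neighbouring genes CPSF2, MRPL36 and TSSK6. In 4 alternatives the list did not stand apart, and with the mean signal over bins it was at percentile 53.4.

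The AMPK list, which holds the kinase's subunits and upstream kinases and regulators of mTORC1, did not stand apart (20 measured, median −0.11, percentile 62.3). Its catalytic subunit gene PRKAA1 stood at −0.14, STK11, the upstream kinase LKB1, at 0.02, TSC2, an inhibitor of mTORC1 signalling, at −0.28, ACACA, acetyl-CoA carboxylase, at −0.19 and ULK1, which starts autophagy, at −0.38. PRKAA2 was below the signal filter, with 49 in the control library and 50 in the metformin library. The largest ratios among measured members were at PPARGC1A, a coactivator of mitochondrial biogenesis (203 and 106, −0.93), and at SESN2, a leucine sensor that is also in the stress response list (530 and 348, −0.61). The promoter region of PRKAG2, a regulatory subunit, was below the filter, with 88 and 47 (−0.89), and is named here after its value was seen. The list of DNA methylation and the methyl donor cycle did not stand apart either (19 measured, −0.11, percentile 60.8). The maintenance methyltransferase DNMT1 stood at −0.07, the de novo enzymes DNMT3A at 0.04 and DNMT3B at −0.53, AHCY, which hydrolyses S-adenosylhomocysteine, at 0.19 and MAT2A, which makes S-adenosylmethionine, at −0.48. The region of the imprinted gene H19 was below the filter, with 63 and 60.

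Other lists did not stand apart. The members named are those with the largest ratios of each list, and some of them lay within the usual scatter at their signal. Among the log2 ratios of regions in the same signal decile, ENO2 lay at percentile 39.3 and SIRT6 at 12.8, while PFKL lay at 98.2. Glycolysis genes lay at percentile 83.6 (19 measured, median −0.08), with PFKL, liver-type phosphofructokinase, at 0.65 and ENO2, a neuronal enolase, at −0.19. Hypoxia genes lay at percentile 14.7 (16 measured, −0.19), with ANGPTL4, an inhibitor of lipoprotein lipase, at −0.59 and BHLHE41, a circadian repressor, at −0.45, but stood apart on the lower side in 4 of 13 alternatives (percentile 1.67 with no filter on signal, 1.65 with a filter at the 75th percentile, 1.59 over all regions of a gene and 1.2 with promoters of 2500 bases). Fatty acid synthesis genes lay at percentile 94.4 (11 measured, −0.03), with SREBF1, which encodes SREBP1, at 0.23 and ELOVL6, a fatty acid elongase, at −0.47. Cell cycle genes lay at percentile 31.0 (30 measured, −0.14), with E2F2, an activator of S phase genes, at −0.66 and CCND3, a D-type cyclin, at −0.51. NF-kB and inflammatory genes lay at percentile 4.49 (9 measured, −0.26), with the chemokine CXCL2 at −0.62 and the inhibitor NFKBIA at −0.49. AP-1 and immediate early genes lay at percentile 7.59 (19 measured, −0.18), with KLF4 at −0.58 and FOS at −0.50, and at percentile 0.24 with the mean signal over bins. Epithelial and mesenchymal genes lay at percentile 82.3 (16 measured, −0.07), with CDH2, N-cadherin, at −0.47 and VIM, vimentin, at −0.36. Among NRF2 targets (15 measured, −0.12, percentile 59.9), TALDO1 of the pentose phosphate pathway stood at −0.67 and the ferritin gene FTH1 at 0.32.

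Autophagy and lysosome genes lay at percentile 15.1 (25 measured, median −0.17), with the kinase ULK2 at −0.65 and the lysosomal hydrolase HEXA at −0.46. Histone and chromatin modifiers lay at percentile 61.9 (26 measured, −0.12), with SUZ12, a core subunit of the Polycomb complex PRC2, at −0.78 and the deacylase SIRT6 at −0.37. Cytosolic ribosomal protein genes lay at percentile 95.4 (45 measured, −0.08), with RPL24 at −0.46 and RPL7 at −0.44. TGF-beta and SMAD genes lay at percentile 25.9 (19 measured, −0.16), with LTBP1, which binds latent TGF-beta, at −0.62 and CCN2, a matricellular protein, at −0.55. YAP and TEAD genes lay at percentile 35.8 (16 measured, −0.16), and the paralogous coactivators went opposite ways, with WWTR1, which encodes TAZ, at 0.87 (71 and 131) and YAP1 at −0.66 (224 and 141). Too few members were measured in the lists of stemness (7), biguanide transporters (2), lung epithelial lineage (2), leukocyte markers (1) and fibroblast and endothelial markers (1). Of these, CD44, a hyaluronan receptor, stood at 0.37, the organic cation transporters SLC22A4 at −0.42 and SLC22A5 at 0.04, the ciliated cell factor FOXJ1 at −0.08, the protease NAPSA at 0.09, CD68 at 0.02 and ACTA2 at −0.05.

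**Figure D3:**
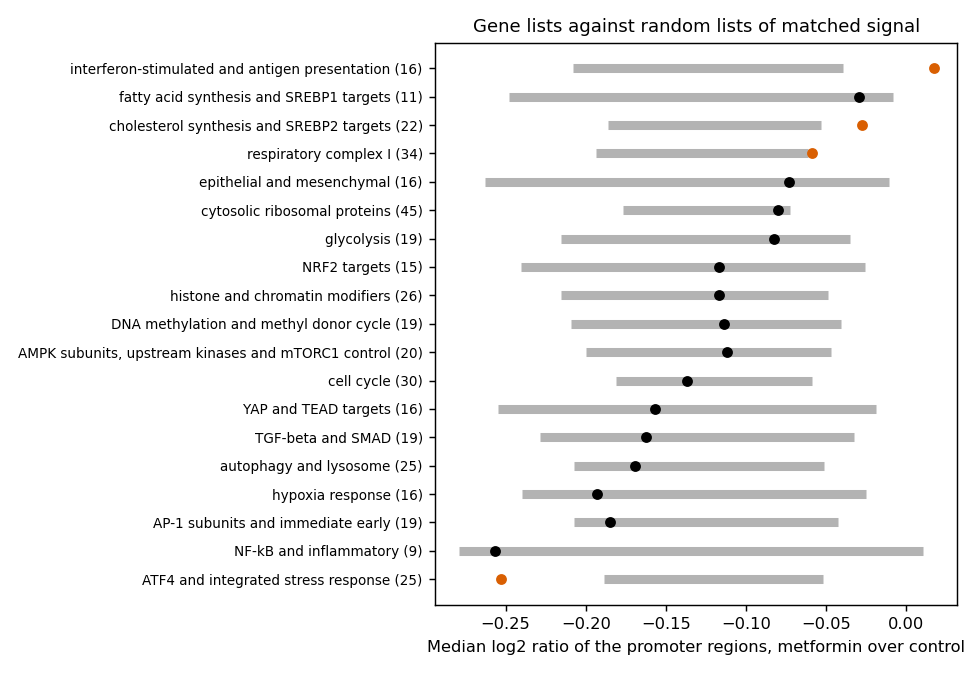
Median log2 ratio of metformin to control over the promoter regions of each gene list (points, x axis), with the number of measured genes in brackets and grey bars for the central 95% of 10000 random lists matched on signal. Orange points mark the 4 lists that stood apart, with the stress response list at −0.25 and the interferon list at 0.02.

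The last question was whether whole chromosomes shifted. Chromosome medians of the log2 ratio ran from −0.13 on chromosome 16 to −0.07 on chromosome 21, a range of 0.062, and chromosome X stood at −0.10. When regions were shuffled among chromosomes 100 times the highest range was 0.051. Chromosome 20, which holds TRIB3 and CEBPB, had a median of −0.11, and chromosome 19, which holds GDF15, −0.08. The ratios at these genes lay far below these medians, but the genes were named for their low ratios. A chromosome median also does not show local shifts.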

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

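The alternatives of shared regions within 500 bases, of list matching on CpG islands and on protein-coding genes, of single counting of shared regions, of subtracting chromosome medians and of the mean signal for lists, the complete versions of the added lists, and the region classes after scaling or in random sets matched on signal, were chosen after seeing the data; the others were planned. With 1 library per treatment, no replicate could be left out. No paired analysis was possible because each treatment has 1 library. The motif comparison and its alternatives were not run. Higher and lower regions numbered 26 and 60 as reported, 47 and 30 with median-ratio scaling and also with lowess centring, 206 and 359 with no filter on signal, 2 and 4 with the filter at the 75th percentile, 233 and 695 at a fold threshold of 1.5, 3 and 6 at a threshold of 3, and 13 and 27 with the mean signal over bins. Scaling moved the boundary against a general shift of −0.10, and the filters and thresholds changed which regions could pass by construction. All 26 higher regions and 30 of the 60 lower ones were called after scaling too. Pseudocount 5 and autosomes alone kept both counts within 1.5 times, and leaving out regions called in 1 library changes nothing, since these had no ratio. Of the regions called in both, in control only and in metformin only, 23557, 284 and 194 had a signal at or above the median, and 17369, 79 and 42 were at least 500 bases long. The promoter minus distal difference kept its sign under every alternative run. It was −0.038 with lowess centring, −0.041 with the filter at the median and −0.034 with that at the 75th percentile. None of these alternatives split regions by CpG island. Among island regions, promoters (−0.136) were not below distal regions (−0.153), and among the others they were only slightly below (−0.080 against −0.064). The pooled difference thus went largely with island content, and its cause was not tested further. The range of chromosome medians was 0.101 with the filter at the 75th percentile and 0.110 over promoter regions only, where fewer regions enter each median. Between 3 and 6 lists stood apart under every alternative. The stress response list (percentile 0 to 0.21) and the interferon list (99.5 to 99.98) did so in 13 of 13 alternatives, and the cholesterol list in 12, all but that over all regions of a gene. Not every alternative could change this outcome. Median-ratio scaling shifts a list and its random lists alike, so its percentiles equal those reported. Single counting of shared regions changed the members of the interferon list only. For the stress response list, matching on length or islands and the limit to protein-coding genes changed the random lists only. Its median stayed at −0.253 with these and with no filter on signal, and was −0.251 with pseudocount 5. The 13 of 13 therefore overstates how far its own values were varied. The complex I list stood apart in 9, and its median minus that of random lists was 0.0029 with the mean signal over bins, where the cause was not tested. The hypoxia list stood apart, on the lower side, in 4 of 13 (lowest percentile 1.2), the AP-1 list in 1 (0.24, mean signal over bins) and the fatty acid list in 1 (99.2, no filter on signal). For the 35 named regions and promoters, 132 of 140 alternative values kept close to those reported, and 8 moved. All 8 came with the mean signal over bins, the only alternative here that used another measurement, and included TRIB3 (−1.27). Median-ratio scaling shifts every ratio by the same amount, and lowess centring and pseudocount 5 changed single values little, so the 132 are weak evidence of stability. The promoters of PMVK and SC5D changed sign, both with the mean signal over bins (−0.20 and −0.0035). Depth limits what can be said of weak regions: the unit of signal is not tied to a number of fragments, and the spread of log2 ratios grew from an SD of 0.14 in the highest decile of signal to 0.44 in the third lowest.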

Other observations

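Chosen only after the result was seen were the tests of counting noise, of GC-rich against GC-poor chromosomes, of lower regions near stress response genes, of the 3 added gene lists, of the lowest decile median as a bound on a trend with signal, and of lists matched on CpG islands or freed of chromosome medians. The genes named in the next 2 paragraphs were also chosen after their values were seen.

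Lower regions not yet named included a region 1031 bases inside PHGDH, the first enzyme of serine synthesis (chromosome 1, 119712585 to 119712998), with signals of 241 in the control library and 103 in the metformin library (log2 ratio −1.22). A region of SLC7A5, a transporter of large neutral amino acids, 15641 bases inside the gene (chromosome 16, 87853622 to 87854037), had 166 and 77 (−1.10). A region assigned to SLC1A5, a glutamine transporter (chromosome 19, 46784733 to 46785129), had 207 and 77 (−1.42), and the promoter region of BCAT1, a branched-chain aminotransferase, 192 and 94 (−1.02). STC2, a stress-induced glycoprotein, had 489 and 344 (−0.51) at a region 1055 bases inside the gene. ATF3, a stress-induced transcription factor, had 412 and 275 (−0.58) at a region inside the gene, 43146 bases from the start that the authors' annotation used. Whether another start of ATF3 lies closer was not analysed here. Other regions near genes of the stress response list went the opposite way, among them regions downstream of ATF4 (125 and 182, 0.54), 1017 bases inside SLC7A5 (221 and 280, 0.34), upstream of WARS1 (150 and 187, 0.32) and inside SLC3A2 (92 and 106, 0.20). Of the 60 lower regions, 4 lay inside or within 10000 bases of the start of a gene of the stress response list (GDF15, PHGDH, SLC7A5 and TRIB3). GDF15 and TRIB3 are the promoters already given for that list, so this count is no separate evidence for it.

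Other regions away from the named set included the highest ratio among those at or above the median signal, on chromosome 1, 8009144 to 8010756, where the signal was 95 in the control library and 355 in the metformin library (1.89). Among higher regions assigned to genes of the fixed lists, a distal region of PRKAG2, a regulatory subunit of AMPK, had 83 and 170 (1.03), opposite to the weak region near its start (88 and 47, −0.89), and a distal region of SCD, stearoyl-CoA desaturase, 91 and 184 (1.01). The promoter region of MGMT, a DNA repair methyltransferase, had 143 and 65 (−1.13). In windows of 50 neighbouring regions, the lowest median was −0.39 on chromosome 8, 141507870 to 143220650, where the lowest of 100 shuffles was −0.35. The highest was 0.17 on chromosome 6, 104683072 to 106445281, which shuffles also gave (0.17).

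The low position of stress response promoters may reflect metformin, and some of its technical alternatives were tested on all 25 measured genes. Against CpG island content, no random list matched on islands as well as signal had so low a median (percentile 0), and against shifts of whole chromosomes, the percentile was 0.06 after chromosome medians were subtracted. Against a trend of the ratio with signal, the list lay 0.13 below random lists of like signal (percentile 0.02, SD of random lists 0.035). Lowess centring also left it 0.13 below, at percentile 0.01. Centring could change little, because these lists were already matched on signal, so it is no separate test. A cruder bound was the lowest median of promoters in any decile of signal (−0.147). It lay inside the bootstrap 95% interval of the list median (−0.43 to −0.13) and decided nothing. What stays open is a difference between the 2 cultures or their libraries other than metformin, such as cell density or exhausted medium. With 1 library per treatment, the cultures and libraries cannot be told apart from the drug. A GC bias stays open too: islands were matched as present or absent only, and the GC content of these promoters was not analysed. Whether related genes were lower too was not shown: cytosolic tRNA synthetases (15 measured) lay at percentile 85.5, amino acid transporters (13) at 17.9 and endoplasmic reticulum chaperones (23) at 38.3, and the first pair, built without members of the stress response list or genes seen among lower regions, lay at 80.0 (16) and 14.0 (17) with these put back.

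The regions at least 2-fold apart could be noise. Poisson draws that took 1 unit of signal as 1 fragment gave at most 1 such region in 100 pairs, against 86 observed, and an SD of the log2 ratio of 0.145, against 0.253. Counting noise stays open all the same, because the number of fragments per unit and the removal of duplicates are not stated. With 2 units per fragment the draws gave a median of 4 regions (highest 11), with 3 units 34 and with 4 units 103. A fixed 3 or 4 units would leave gaps between possible signals. Signals in the metformin library among the 86 regions include 70, 71, 72, 73, 74 and 75. These argue against such a fixed number, but not against uneven numbers per fragment, as with duplicates. The bound set for this test, under 1 unit per fragment, therefore excludes nothing. Noise independent between regions stays open too: Spearman's rank correlation of neighbours 1 to 10 kb apart was 0.038 (highest of 100 shuffles 0.037), 10 to 50 kb apart 0.052 (0.027), 50 to 200 kb apart 0.044 (0.032) and 200 to 1000 kb apart 0.033 (0.063), so the ratios were not wholly independent, but these weak relations over all regions do not decide for the 86. Single regions among the 86 may differ by chance, and replicate libraries would be needed to tell which.

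The lower ratio of CpG island regions, by −0.07 against other regions, may come from the sequence or from the position of islands. Against their higher signal, the mean difference within deciles of signal was −0.088, and it was below 0 in all 10 deciles. Against promoter position, the difference among regions over 1000 bases from any start was −0.075. A GC bias of the libraries stays open: regions without an island on GC-rich chromosomes differed from those on GC-poor ones by −0.0075 (bootstrap 95% interval −0.027 to 0.011), which decides neither way, and GC content itself was not analysed here. Metformin as the reason is untested for the same lack of replicates.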
